A study of Mus musculus with 8 samples.

How the data were processed

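RNA of sorted mouse B cells was sequenced as 8 libraries, 4 of IL-10+ and 4 of IL-10- cells. Per the labels, B cells purified from spleens of IL-10 reporter mice received lipopolysaccharide at 3 µg/ml, were sorted after 48 h, and gave libraries by a NEBNext Ultra kit from RNA extracted with Trizol. A treatment tag in the labels reads untreated, which stands against these protocols, and the protocols were followed. Each library's group and replicate number came from its title, and each column of the table was matched to a library by the column name given in that library's description.

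The deposited table holds FPKM values made by the authors, that is, read counts divided by gene length and by the library's read total, for 26589 genes. Per the submitters' processing notes, the tools were HISAT2 2.1.0 and HTSeq 0.6.0 and the genome build was mm10. The annotation release, the strand setting and the handling of reads shared between genes are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. Gene names and positions came from the GENCODE M21 annotation of GRCm38, the same build as mm10, in which 26517 of the identifiers were found and 72 were not. In each library 93.4% to 93.6% of the values above 0, multiplied by gene length and by a single library total, gave whole reads within 0.05. This gave library totals between 27380388 and 29968276 reads, and 1 read in 1 kb is worth 0.0334 to 0.0365 FPKM. No 2 libraries of the same group were near-copies, since the chi-square per degree of freedom of recovered reads between libraries of a group was 9.82 to 92.2.

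FPKM are not counts, so the groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a pseudocount of 1 and a variance trend, over the 11329 genes with at least 1 FPKM in at least 4 libraries. Fold changes on this scale understate changes of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A fold named without a log2 scale is the ratio of the group means in FPKM. Counts of genes changed 2-fold or more are the exception and take an absolute log2 change of FPKM + 1 of at least 1. The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined, and the replicate number was left out of the planned fit. The numbers were then checked. Deviations from the group means correlated at 0.71, 0.58, 0.62 and 0.70 between libraries of the same number, across genes, and each library correlated best with its own number, so by the rule set beforehand the numbers pair the samples. This pairing comes from the data and not from the labels. Values with the number as a block are given where they change a call or move a count by more than 1.5 times.

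Gene lists for 44 themes were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 43 lists with a measured member; neutrophil markers had none. Camera asks whether a list's genes moved further than other genes, and fry served as a description of whether a list moved at all. With the preset correlation 13 lists passed, 7 up and 6 down. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), 15 passed with the block and the preset correlation, and 13 passed in fry. The 13 lists of fry were not all those of camera. Lists can share members, so they are not independent. Prdm1 is in the plasmablast and Il10 regulator lists, Cd9 in the regulatory and marginal zone lists, and Fcer2a in the mature and follicular lists. Replicates 1 and 2 were compared with 3 and 4 on the mean of the 2 libraries of each number, 2 numbers against 2. Single values were compared with exact two-sided permutation tests, which exchange libraries without regard to their replicate numbers.

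Named genes were Il10 and Mapk3, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in a group and no overlap between groups, leaving out predicted genes and immunoglobulin segments. In each list up to 4 called members with the largest change were taken, with up to 2 of the most abundant where fewer than 2 passed, and 3 of the most abundant for lists of other cell types. Of the uncalled members this rule takes, some are given in the text with their values and the rest are left out for length. Some items that the rule takes are not reported here. Other genes named in the text, among them members that complete a small count, the V segments and the genes that differ between replicate numbers, were chosen after their values were seen.

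The fit was tested on simulated data over the same 11329 genes. Without the block it called 49.3% of 67, 82.1% of 67 and 98.5% of 66 genes changed by a log2 of 0.5, 1 and 2, with 6 false calls. With variance shared within a replicate number, the unblocked fit called 56.7% and the blocked fit 76.1% of those changed by 0.5, with 0 and 9 false calls. Alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, 3 other scalings of the libraries, a robust fit, library weights, the block, a threshold of 0.01, and fits that left out each library and each replicate number. The fits that left out libraries had no block, so spread between replicate numbers stayed in their residuals. Added after seeing the data were voom on the recovered reads, combinations of scaling and block, and fits within replicates 1 and 2 and within 3 and 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.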

Results

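Messenger RNA was profiled in 8 bulk RNA-seq libraries of mouse splenic B cells, 4 of IL-10+ cells and 4 of IL-10- cells. The cells came from IL-10-eGFP Tiger mice, a reporter strain in which cells that transcribe Il10 make green fluorescent protein. Purified B cells were cultured for 48 h with 3 µg/ml lipopolysaccharide, a bacterial ligand of Toll-like receptor 4, and were then sorted on the reporter. The library totals recovered from the deposited FPKM values (read counts scaled by gene length and by the library's read total) lay between 27380388 and 29968276 reads, so that 1 read in a transcript of 1 kb was worth 0.0334 to 0.0365 FPKM. Between 20308 and 21378 genes had a value above 0 in a library. The labels number the replicates 1 to 4 in each group without saying whether a number marks a mouse or a culture. The p-values therefore measure the spread between these libraries, which may be partly technical. The series title concerns oxidative phosphorylation and the ERK pathway in IL-10 production, and the comparison asks which transcripts differ between cells sorted as IL-10+ and as IL-10-.

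Il10, the gene the cells were sorted on, checks the labels and is no finding. It lies on chromosome 1 at 131019845 to 131024974 of GRCm38 (ENSMUSG00000016529). Il10 stood at 36.9 ± 5.32 FPKM (SD, n = 4) in IL-10+ and 3.17 ± 1.48 FPKM (SD, n = 4) in IL-10- cells, an 11.6-fold ratio of the means. The recovered reads for Il10 were 1148 to 1628 in the IL-10+ libraries and 47 to 187 in the IL-10- libraries. The IL-10- libraries were thus low in Il10 and not without it. Bulk libraries do not show which of the sorted cells gave these reads. The log2 change of FPKM + 1 was 3.25 (SE 0.260, adjusted p = 6.35e-05). An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. Il10 was higher in the IL-10+ library of each of the 4 replicate numbers.

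Across the transcriptome, 2236 of the 11329 tested genes differed between the groups, of which 1196 rose and 1040 fell in IL-10+ cells. Of these, 399 rose and 69 fell by 2-fold or more on the scale of FPKM + 1. Immunoglobulin segments were 224 of the genes that rose and 214 of those that rose by 2-fold or more, and 1 of the 245 tested segments fell. Among the other genes 972 rose and 1039 fell, and 185 and 68 of them did so by 2-fold or more. In 2855 genes (25.2%) the 4 values of one group did not overlap those of the other, against 2.86% by chance. Libraries with the same replicate number deviated together, and a fit with the number as a block called 6083 genes (2312 higher, 3771 lower), including all 2236 in the same direction. The excess of falls was smaller when the block was combined with median-of-ratios scaling (2615 higher, 3009 lower) or with scaling without immunoglobulin and mitochondrial genes (2550 higher, 3116 lower). Replicates 1 and 2 stood apart from 3 and 4 in both groups. Within replicates 1 and 2 alone 1106 genes passed, and within 3 and 4 alone 2647 passed, and the log2 change of Il10 was 3.71 and 2.80 in these sets.

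**Figure D1:**
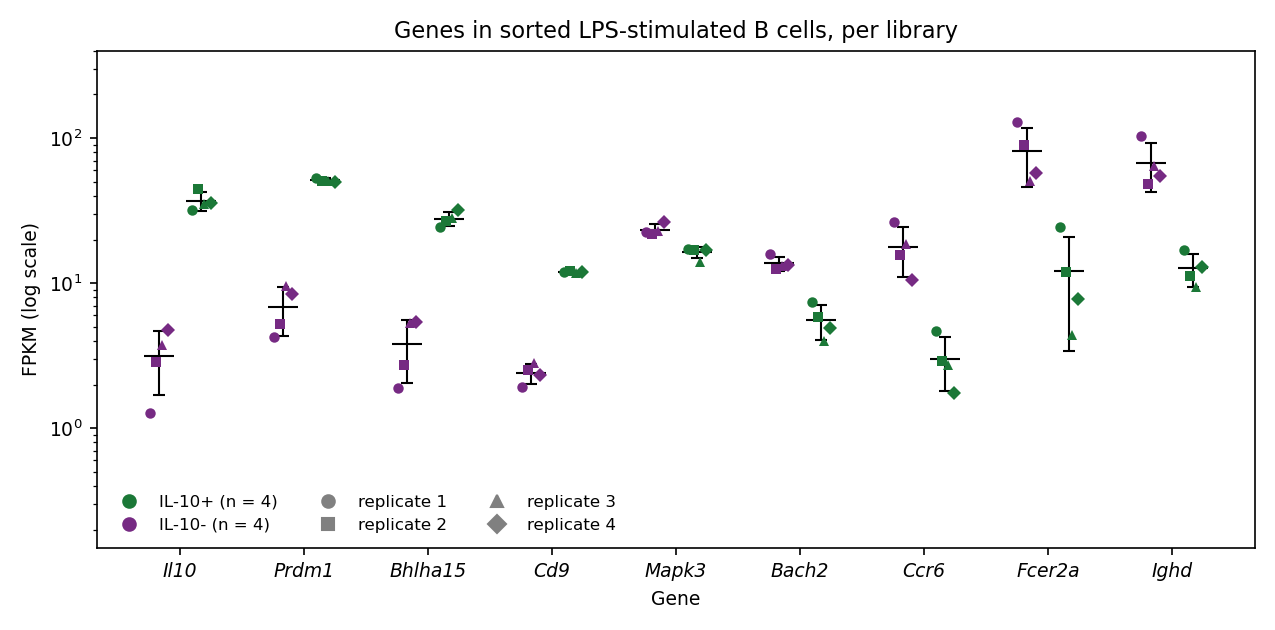
Expression (FPKM, log scale) of 9 genes in each library, with purple for IL-10- and green for IL-10+ cells, symbols for the replicate numbers, and black bars for the mean ± SD of 4 libraries. The groups are fully apart for all 9, with Il10 at 36.9 FPKM in IL-10+ and 3.17 FPKM in IL-10- cells.

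The 10 largest rises under the rule for named genes, which leaves out immunoglobulin segments, included regulators and machinery of antibody secretion. Prdm1, which encodes the plasma cell regulator Blimp-1 (chromosome 10, 44437177 to 44528501), stood at 51.1 ± 1.61 FPKM in IL-10+ and 6.89 ± 2.54 FPKM in IL-10- cells (SD, n = 4), 7.42-fold apart (log2 change 2.78, SE 0.209, adjusted p = 5.03e-05). Bhlha15, the secretory cell factor Mist1, was 7.27-fold higher. Jchain, the joining chain of polymeric IgM and IgA, rose from 10.5 ± 1.38 to 72.1 ± 36.2 FPKM. The others besides Il10 were Hid1 (7.68-fold), Il5ra (6.94-fold), Creb3l2 (6.58-fold), Sec24d (6.18-fold), Tent5c (5.32-fold) and Derl3 (4.87-fold). Hid1 acts in secretory granule formation, Il5ra is the interleukin-5 receptor α chain, and Creb3l2 is a transcription factor of the secretory pathway. Sec24d belongs to the COPII coat that carries cargo out of the endoplasmic reticulum, and Derl3 acts in the removal of misfolded proteins from it. Each of these genes was higher in 4 of 4 replicate numbers, which the rule fixes in advance, since it takes only genes without overlap between groups.

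In the list of plasmablast and plasma cell genes, 23 of 25 measured members rose and none fell, and the count was the same when adjusted over the list alone. Its median log2 change was 1.57 (camera adjusted p = 4.04e-21). In the list of the unfolded protein response and secretion, 42 of 47 members rose and none fell, or 44 when adjusted over the list alone, with a median log2 change of 0.98 (camera adjusted p = 2.68e-31). Examples were the chaperone gene Hsp90b1, at 353.9 ± 63.2 against 124.5 ± 43.9 FPKM, and Creld2, at 173.6 ± 30.8 against 55.0 ± 20.6 FPKM (SD, n = 4). With an estimated correlation the adjusted p was 0.153 for the plasmablast list and 0.353 for the secretion list. In the exact permutation test of the mean list level, both gave p = 0.0286. The other 11 lists that passed camera gave the same value, except for the MHC class II and the G2 and M phase lists (exact p = 0.0571), the NF-κB targets (exact p = 0.114) and the amino acid and ATF4 list (exact p = 0.371). This test exchanges libraries without regard to their replicate numbers, so spread between the numbers enters all these values. In each number the NF-κB list was lower in IL-10+ cells (differences -0.462 to -0.295) and the ATF4 list higher (0.287 to 0.476). No exact test within the numbers was run. At the preset correlation, the plasmablast list passed in each set of replicates. Its camera adjusted p was 3.31e-23 within 1 and 2 and 2.19e-19 within 3 and 4. Each set holds 2 libraries per group, and for no list was an estimated correlation used within the sets.

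Immunoglobulin transcripts took 14.6% ± 1.62 of the summed FPKM in IL-10+ and 4.19% ± 0.439 in IL-10- libraries (SD, n = 4). Among the constant regions, Ighm stood at 10992 ± 1797 against 2940 ± 328 FPKM, Igkc at 9773 ± 1523 against 2533 ± 327 FPKM and Iglc1 at 397.8 ± 27.5 against 115.4 ± 9.89 FPKM. Ighd, which encodes IgD of resting B cells, fell from 67.5 ± 24.8 to 12.6 ± 3.23 FPKM. Of the 12 measured members of this list 6 rose and 1 fell (6 and 3 adjusted over the list alone; 6 and 4 with the block; camera adjusted p = 0.0128, adjusted p = 0.938 with an estimated correlation, 0.193 with the replicate block, 0.0694 without a filter on low values, 0.0521 without IL-10+ replicate 1 and 0.111 within replicates 3 and 4). Of the 196 measured V segments 192 rose and none fell, with a median log2 change of 1.89. The 4 with the largest change, singled out after their values were seen, were Ighv11-2 (287.7 ± 88.7 against 3.65 ± 0.522 FPKM), Igkv14-126 (615.5 ± 146.5 against 17.04 ± 2.75 FPKM), Ighv12-3 (211.5 ± 47.2 against 6.65 ± 2.76 FPKM) and Igkv4-91 (272.7 ± 31.9 against 23.9 ± 3.65 FPKM). Reads of V segments can be shared between close relatives, and how the authors counted such reads is not given in the sources used here.

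**Figure D2:**
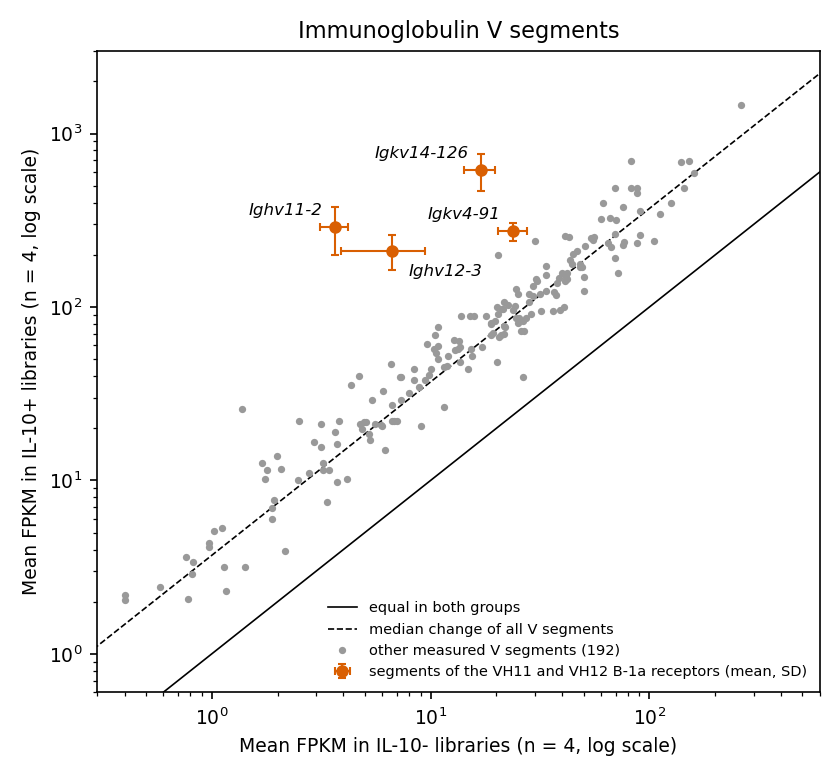
Mean FPKM of each measured immunoglobulin V segment in IL-10- (horizontal) and IL-10+ libraries (vertical), both on log scales, with 4 segments in orange (± SD, n = 4) and the other 192 in grey. The solid line marks equal levels and the dashed line the median change of all V segments, and Ighv11-2, at 3.65 against 287.7 FPKM, lies farthest above it.

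The 10 largest falls under the same rule included several surface receptors of B cells. Fcer2a, the low-affinity IgE receptor CD23, fell from 81.9 ± 36.0 to 12.1 ± 8.68 FPKM (SD, n = 4; log2 change -2.80, SE 0.473, adjusted p = 0.00365), and Ccr6, a chemokine receptor, from 17.7 ± 6.62 to 3.02 ± 1.22 FPKM. Ms4a4c was 4.33-fold lower. Icosl, the ligand of the T cell costimulator ICOS, was 6.02-fold lower, and the surface receptor gene Slamf1 was 4.38-fold lower. Zfp318, which is needed for the IgD transcript, was 3.44-fold lower. Lfng (3.51-fold), Serpinb1a (2.95-fold), Sorl1 (2.95-fold) and B3gnt5 (2.78-fold) were the others. Each was lower in the IL-10+ library of all 4 replicate numbers, which the rule's demand for no overlap between groups also fixes in advance.

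Of 32 mature B cell identity genes, 17 fell and none rose (22 fell and 1 rose adjusted over the list alone; 27 fell and 3 rose with the replicate block), with a median log2 change of -0.48 (camera adjusted p = 2.63e-06, adjusted p = 0.938 with an estimated correlation). Bach2, a repressor that opposes plasma cell differentiation, fell from 13.7 ± 1.48 to 5.56 ± 1.47 FPKM, and Spib, an ETS factor of B cells, from 162.4 ± 28.0 to 73.3 ± 19.6 FPKM. Cd72, a co-receptor of B cells, was 2.36-fold lower (adjusted p = 0.0253). Its call ended in 4 of the 8 unblocked fits that left out 1 library (adjusted p up to 0.0692). With all libraries and the block its adjusted p was 8.80e-05. At the preset correlation this list passed within replicates 1 and 2 (adjusted p = 2.59e-08) and within 3 and 4 (adjusted p = 1.09e-06). Among 13 follicular B cell genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; 11 and 1 with the block), with camera adjusted p = 0.00346 and adjusted p = 0.938 with an estimated correlation.

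The list of MHC class II antigen presentation genes, which also holds costimulatory genes such as Cd40, Cd80 and Icosl, passed as lower in IL-10+ cells. Icosl had the list's lowest log2 change (-1.72). Of 16 measured members 7 fell and 1 rose (9 and 1 adjusted over the list alone; 14 and 1 with the block), with a median log2 change of -0.65 (camera adjusted p = 0.00104, adjusted p = 0.938 with an estimated correlation). Cd40, the receptor for T cell help, fell from 38.7 ± 3.94 to 19.0 ± 1.64 FPKM. The peptide-exchange genes H2-DMb2 and H2-Oa were 1.97-fold and 2.71-fold lower. The call of H2-DMb2 ended in 4 of the 8 fits that left out 1 library (adjusted p up to 0.0740), and that of H2-Oa ended without IL-10+ replicate 3 (adjusted p = 0.0534) and without IL-10- replicate 2 (adjusted p = 0.0511). The member that rose was the costimulator Cd80.

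The lists of NF-κB targets and type I interferon response genes passed as lower at the preset correlation, and the list of cytokines and chemokines did not pass. Of 23 NF-κB targets 9 fell and 2 rose (12 and 3 adjusted over the list alone; 19 and 3 with the block), with camera adjusted p = 0.00919, adjusted p = 0.938 with an estimated correlation and a fry adjusted p of 0.102. Cd83 fell from 120.2 ± 26.7 to 46.7 ± 16.8 FPKM, Tnf from 10.5 ± 1.06 to 4.76 ± 1.02 FPKM and Lta from 3.78 ± 0.737 to 1.06 ± 0.514 FPKM (SD, n = 4). Cxcl10 went the other way, from 1.87 ± 0.699 to 5.09 ± 1.98 FPKM, and lost its call without IL-10- replicate 3 (adjusted p = 0.0513) or IL-10- replicate 4 (adjusted p = 0.0524). Of 24 type I interferon response genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; 17 and 4 with the block), with camera adjusted p = 0.00537 and adjusted p = 0.938 with an estimated correlation. Ifit3 was 3.00-fold lower and Oas3 2.19-fold lower. Oas2 was 2.57-fold lower, with adjusted p up to 0.0543 when 1 library was left out and its call ended in 3 of 8 such fits. The exonuclease gene Isg20 was 2.14-fold higher. Of 14 measured cytokines and chemokines 2 rose, Il10 and Cxcl10, and 4 fell (3 and 5 adjusted over the list alone; 3 and 8 with the block), with camera adjusted p = 0.521.

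**Figure D3:**
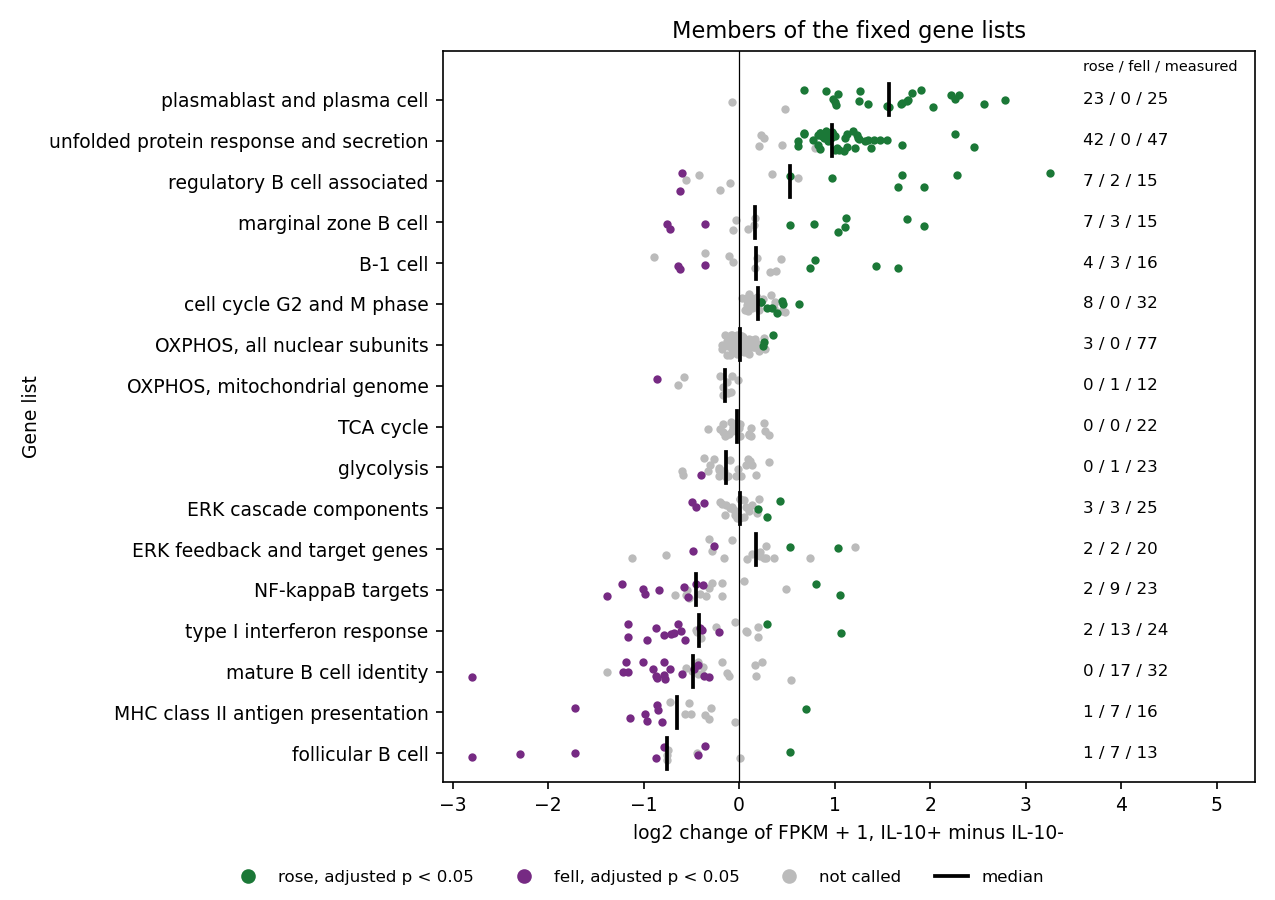
Log2 change (IL-10+ minus IL-10-, of FPKM + 1) of each measured member of 17 gene lists fixed before the data were examined, with 1 point per gene, green and purple for genes past the threshold, grey for the others and a black line at the list's median. The plasmablast list lies right of 0 with 23 of 25 members higher. The follicular, MHC class II and mature B cell lists lie left of 0. The nuclear OXPHOS and ERK cascade lists each have a median of 0.01. The mitochondrial OXPHOS list has a median of -0.15 and the list of ERK feedback and target genes one of 0.18.

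The list of genes associated with regulatory B cells rose in part. It holds Il10 itself, so its direction is partly set by the sort. Of 15 measured members 7 rose and 2 fell (8 and 2 adjusted over the list alone; 9 and 5 with the block), with a median log2 change of 0.53 (camera adjusted p = 0.00537, adjusted p = 0.938 with an estimated correlation, 0.155 with only genes of at least 5 FPKM, 0.0793 with median-of-ratios scaling and the block, and 0.0709 with scaling without immunoglobulin and mitochondrial genes and the block). Besides Il10 and Il5ra, the tetraspanin Cd9 rose from 2.40 ± 0.379 to 11.9 ± 0.173 FPKM and the inhibitory receptor Lag3 from 1.19 ± 0.298 to 6.32 ± 2.35 FPKM (SD, n = 4). The 2 that fell were Tgfb1 and Pdcd1lg2. At the preset correlation the list passed within replicates 1 and 2 (adjusted p = 0.0203) and within 3 and 4 (adjusted p = 0.0106).

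Marginal zone genes moved in both directions. Of 15 members 7 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.938 with an estimated correlation, and 0.327 with only genes of at least 5 FPKM). Mzb1, an endoplasmic reticulum protein of antibody-secreting cells, stood at 889.2 ± 24.6 against 265.2 ± 44.7 FPKM, Gpr55 was 2.60-fold higher and Myof 3.87-fold higher. The complement receptor Cr2, Notch2 and Fcrl5 fell. Of 16 B-1 cell genes 4 rose and 3 fell (6 and 3 adjusted over the list alone; 8 and 5 with the block), with camera adjusted p = 0.189. Vim, Zcwpw1 and Fcrl5 fell, and the risers were Ctla4 (5.61-fold), Spn, which encodes CD43 (2.97-fold), Bhlhe41 (2.18-fold) and Ptpn22 (1.76-fold). Of 22 regulators of Il10 transcription 3 rose and 3 fell (3 and 6 adjusted over the list alone; 5 and 11 with the block), with camera adjusted p = 0.701. The median of this list was -0.16 and its mean 0.01. Prdm1, described above with the largest rises, had the list's largest rise. Irf4 rose from 58.5 ± 5.47 to 143.0 ± 18.6 FPKM, and Batf fell from 116.9 ± 7.09 to 65.7 ± 11.4 FPKM. Among 30 checkpoint and adhesion molecules 6 rose and 9 fell (7 and 10 adjusted over the list alone; 10 and 16 with the block; camera adjusted p = 0.747). The chemokine receptor Cxcr4 was 3.58-fold higher and the checkpoint ligand Cd200 was 2.78-fold lower.

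Transcripts of the respiratory chain differed little between the groups. Of 77 measured nuclear genes for subunits of complexes I to V, 3 rose and none fell (1 and 0 adjusted over the list alone), and the median log2 change was 0.01 (camera adjusted p = 0.409). With the replicate block 14 rose and 8 fell (camera adjusted p = 0.178), and the list passed as higher when the block was combined with median-of-ratios scaling (adjusted p = 0.0219) or with scaling without immunoglobulin and mitochondrial genes (0.0327). The 3 were Ndufa1 (65.1 ± 2.01 against 50.8 ± 2.58 FPKM, SD, n = 4) and Ndufb11 of complex I, and Uqcrq of complex III, at 1.28-fold, 1.20-fold and 1.19-fold. The call of Ndufb11 ended in 6 of the 8 fits that left out 1 library (adjusted p up to 0.0877) and that of Uqcrq in 4 (adjusted p up to 0.0849). Without IL-10+ replicate 1, the list as a whole passed in the upward direction (adjusted p = 0.0231), and without IL-10- replicate 1 its direction turned (adjusted p = 0.603). It gave adjusted p = 0.305 within replicates 1 and 2 and 0.353 within 3 and 4. With an estimated correlation and no other scaling, its camera adjusted p was 0.938 without the block and 0.782 with it.

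By complex, the number of members that rose was 2 of 36 for complex I (1 adjusted over the list alone), 0 of 4 for complex II (1), 1 of 10 for complex III (1), 0 of 11 for complex IV (0) and 0 of 16 for complex V (0), and none fell. With the block these lists had 6 higher and 4 lower for complex I, 1 and 1 for complex II, 3 and 0 for complex III, 2 and 1 for complex IV and 2 and 2 for complex V. Their camera adjusted p lay between 0.483 and 0.969. Limma called 0 genes in complexes II, IV and V, with 1, 0 and 0 at an unadjusted p under 0.05, and voom called 1, 0 and 0. The median, mean and camera direction differed in sign for complex II (-0.05, 0.0017 and up) and complex V (-0.03, -0.0074 and up). Among them the subunits Sdha (83.8 ± 7.81 against 92.9 ± 7.87 FPKM), Cox6a1 (383.4 ± 22.9 against 341.4 ± 46.2 FPKM) and Atp5a1 (388.7 ± 37.2 against 412.9 ± 40.7 FPKM) passed with the replicate block (adjusted p = 0.00416, 0.0377 and 0.0326). Of 12 measured genes of the mitochondrial genome 1 fell, none adjusted over the list alone and 7 with the block (camera adjusted p = 0.252). It was mt-Co3, at 15.9 ± 6.34 against 28.6 ± 4.56 FPKM, and its call ended in 6 of the 8 fits that left out 1 library (adjusted p up to 0.0863). The more abundant mt-Co1 stood at 7433 ± 1106 against 7521 ± 1245 FPKM (log2 change -0.01, adjusted p = 0.960), and it passed as lower with quantile normalization (log2 change -0.85, adjusted p = 5.95e-06). This list passed as lower without IL-10- replicate 2 (adjusted p = 0.0427) and within replicates 3 and 4 (adjusted p = 0.0310), though not within 1 and 2 (adjusted p = 0.632).

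The level of the respiratory chain genes followed the replicate numbers more than the sort. The mean log2 level of the 77 nuclear genes was 5.18 to 5.43 in the libraries of replicates 1 and 2 and 5.55 to 5.57 in those of replicates 3 and 4, and with the mean of the 2 libraries of each number as the unit, 2 numbers against 2, 7 of the 77 were higher in replicates 3 and 4 and 1 lower (camera adjusted p = 1.27e-10, adjusted p = 0.550 with an estimated correlation).

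**Figure D4:**
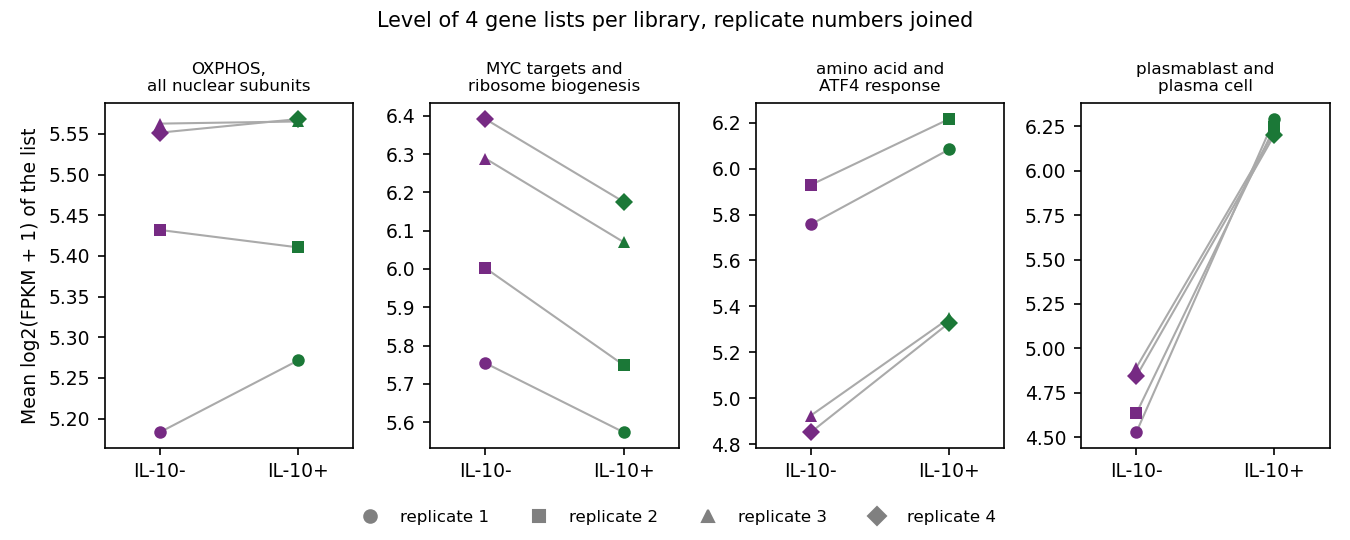
Mean log2(FPKM + 1) of 4 gene lists in each library, IL-10- at the left and IL-10+ at the right of each panel, with lines joining libraries of the same replicate number. Each panel has its own axis range. The plasmablast list is higher in IL-10+ cells in all 4 replicate numbers, while the OXPHOS list lies at 5.18 to 5.43 for replicates 1 and 2 and at 5.55 to 5.57 for replicates 3 and 4 in both groups.

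Other metabolic lists held few calls without the block. Of 22 TCA cycle genes 0 passed in limma, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05; 1 in voom), and 6 rose and 6 fell with the block (camera adjusted p = 0.894). The median and mean of this list were -0.03 and -0.01, with an upward camera direction. Of 23 glycolysis genes 1 fell (0 adjusted over the list alone; 4 higher and 12 lower with the block; camera adjusted p = 0.483). It was Pfkfb4, 1.52-fold lower, and its call ended in 6 of the 8 fits that left out 1 library (adjusted p up to 0.0964). Pkm stood at 354.7 ± 29.9 against 313.7 ± 28.1 FPKM (adjusted p = 0.217, or 0.00320 with the block). Of 17 fatty acid oxidation genes 2 fell, Slc25a20 and Acadm (2 adjusted over the list alone; 5 higher and 3 lower with the block; camera adjusted p = 0.747), and each lost its call in 6 of 8 such fits (adjusted p up to 0.0941 and 0.0980). The median of this list was -0.03 and its mean 0.0090. Of 42 genes of mitochondrial ribosomes and biogenesis 2 fell, Ppargc1b and Esrra (0 adjusted over the list alone; 3 higher and 19 lower with the block; camera adjusted p = 0.379, or 0.0148 without IL-10- replicate 1). Ppargc1b lost its call without IL-10+ replicate 2 (adjusted p = 0.0525) or IL-10- replicate 4 (adjusted p = 0.0510), and Esrra in 7 of 8 such fits (adjusted p up to 0.105).

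Lists of growth and metabolism changed calls with the replicate block. Of 32 MYC target and ribosome biogenesis genes 0 passed in the unblocked limma fit, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05; 0 in voom), and 29 fell and 2 rose with the block (camera adjusted p = 0.0524 unblocked and 7.66e-06 blocked). The MYC list also passed as lower within replicates 1 and 2 (adjusted p = 0.00388), within 3 and 4 (5.45e-05), with voom (0.0434), under the 3 other scalings (0.00525 to 0.0354), with library weights (0.00765), without a filter on low values (0.00321), and without IL-10+ replicate 3 (0.0101), IL-10+ replicate 4 (0.00333), IL-10- replicate 1 (0.00109) or IL-10- replicate 2 (0.0284). Npm1, a nucleolar chaperone, stood at 703.2 ± 67.6 against 819.9 ± 81.5 FPKM (SD, n = 4; blocked adjusted p = 0.00372). Of 21 cholesterol synthesis genes 0 passed in limma, also adjusted over the list alone (1 at an unadjusted p under 0.05; 0 in voom), and 18 fell and 1 rose with the block (camera adjusted p = 0.379 and 0.000978). This list passed as lower without IL-10+ replicate 4 (adjusted p = 0.0485) or IL-10- replicate 1 (0.0338). Insig1, which holds back sterol synthesis, was the exception, at 89.2 ± 20.3 against 65.4 ± 17.5 FPKM (blocked adjusted p = 0.000412). Of 17 antioxidant genes 3 rose (1 adjusted over the list alone), and 11 rose and 2 fell with the block (camera adjusted p = 0.121 and 0.0218, and 0.0328 without IL-10+ replicate 1). Hmox1, heme oxygenase 1, rose from 4.65 ± 1.60 to 14.9 ± 1.89 FPKM, while the calls of Nqo1 and Gsr ended in 7 and 6 of the 8 fits that left out 1 library (adjusted p up to 0.10 and 0.118). With an estimated correlation and the block, the adjusted p was 0.512 for the MYC list and 0.497 for the cholesterol and antioxidant lists.

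The amino acid and ATF4 list passed as higher (camera adjusted p = 0.0123, adjusted p = 0.938 with an estimated correlation, fry adjusted p = 0.496, and 0.0576 with quantile normalization), although only 1 of its 21 members, the amino acid transporter Slc7a5, passed by itself. None passed adjusted over the list alone, and 17 rose with the block. Slc7a5 stood at 269.9 ± 54.8 against 166.7 ± 36.7 FPKM (SD, n = 4), and its call ended in 5 of the 8 fits that left out 1 library (adjusted p up to 0.0940). Atf4 itself stood at 449.3 ± 54.2 against 370.7 ± 75.7 FPKM (adjusted p = 0.211, or 0.00572 with the block). The list lost its call without IL-10+ replicate 1 (adjusted p = 0.0522), IL-10+ replicate 2 (0.109), IL-10- replicate 3 (0.0793) or IL-10- replicate 4 (0.115). These fits had no block. At the preset correlation the list passed with the block (camera adjusted p = 1.27e-06), within replicates 1 and 2 (0.000475) and within 3 and 4 (4.35e-08). With the block and an estimated correlation its adjusted p was 0.497.

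Mapk3, which encodes the kinase ERK1 (chromosome 7, 126759601 to 126765819), fell in IL-10+ cells. Mapk3 stood at 16.3 ± 1.48 FPKM in IL-10+ and 23.4 ± 2.02 FPKM in IL-10- cells (SD, n = 4), 1.43-fold lower (log2 change -0.50, SE 0.0876, adjusted p = 0.00450; exact two-sided permutation p = 0.0286). Within replicates 1 and 2 its adjusted p was 0.0659, and within 3 and 4 it was 0.0246. Of 25 components of the ERK cascade 3 rose and 3 fell (3 and 4 adjusted over the list alone; 6 and 6 with the block), and the list did not pass as a whole (camera adjusted p = 0.894, median log2 change 0.01, mean -0.02). The kinase gene Map3k8 (1.39-fold), Shc1 and Rps6ka3 rose, and the RasGAP gene Rasal3 (1.39-fold) and the adaptor gene Grb2 (1.29-fold) fell. Map3k8 lost its call without IL-10+ replicate 4 (adjusted p = 0.0511) or IL-10- replicate 2 (0.0529), and Grb2 in 3 of the 8 fits that left out 1 library (adjusted p up to 0.0623).

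Of 20 measured ERK feedback and target genes 2 rose and 2 fell, also when adjusted over the list alone (7 and 7 with the block; camera adjusted p = 0.517). Etv5, an ETS factor induced by ERK, rose from 2.61 ± 0.417 to 4.2 ± 0.462 FPKM. The phosphatase gene Dusp4 was 2.12-fold higher, while the phosphatase gene Dusp2 was 1.42-fold lower and Elk1 1.26-fold lower. Each of these last 3 lost its call in 6 of the 8 fits that left out 1 library (adjusted p up to 0.10, 0.0946 and 0.105). These are transcript levels, and the phosphorylation of ERK was not measured in these libraries.

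Proliferation genes were compared by phase, and the difference between the phases was not tested. Of 32 G2 and M phase genes 8 rose and none fell (9 adjusted over the list alone; 23 with the block), with a median log2 change of 0.20 (camera adjusted p = 6.52e-06, adjusted p = 0.938 with an estimated correlation). Mki67 rose from 108.8 ± 3.27 to 149.2 ± 2.91 FPKM (SD, n = 4). Cdc20 (1.53-fold), Ube2c (1.38-fold) and Cdca3 (1.32-fold) were higher, and their calls ended in 4, 3 and 3 of the 8 fits that left out 1 library (adjusted p up to 0.0772, 0.0628 and 0.0594). Of 30 S phase genes 6 fell (7 adjusted over the list alone; 4 higher and 19 lower with the block; camera adjusted p = 0.0932, or 0.0158 with the block and 0.497 with the block and an estimated correlation). The S phase list also passed with quantile normalization (adjusted p = 0.0257), library weights (0.0275) or no filter on low values (0.00531), and without IL-10+ replicate 3 (adjusted p = 0.0212), IL-10+ replicate 4 (0.0289) or IL-10- replicate 1 (0.00299). It passed within replicates 3 and 4 (camera adjusted p = 0.0138) and did not pass within 1 and 2 (0.108). Rfc2 was 1.31-fold and Chaf1b 1.35-fold lower. E2f1 (1.42-fold) and Uhrf1 (1.35-fold) each lost their call in 7 of 8 such fits (adjusted p up to 0.0883 and 0.112). Of 8 measured canonical histone genes 2 rose, Hist1h1c (3.06-fold) and Hist1h2bc (3.33-fold), also when adjusted over the list alone (2 higher and 1 lower with the block; camera adjusted p = 0.50). The histone list was set as a check of library quality, not of proliferation. Its median was -0.05 and its mean 0.20.

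Of 24 apoptosis regulators 1 rose and 4 fell, also when adjusted over the list alone (5 and 11 with the block; camera adjusted p = 0.483). The survival gene Bcl2l1 rose from 11.8 ± 2.69 to 21.1 ± 1.87 FPKM, and its relative Bcl2a1d fell from 142.2 ± 21.8 to 62.7 ± 20.9 FPKM (SD, n = 4). Casp9 was 1.4-fold lower. Bcl2a1b was 2.17-fold lower, and its call ended in 4 of the 8 fits that left out 1 library (adjusted p up to 0.0578). Bcl2a1b and Bcl2a1d are near-identical copies whose reads can be shared, so their separate values are uncertain. Of 17 stress and heat shock genes 0 passed in limma, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05; 0 in voom), and 4 rose and 7 fell with the block (camera adjusted p = 0.826). Its median was -0.05 and its mean 0.0097. Hspa8 stood at 517.9 ± 218 against 652.3 ± 227 FPKM (adjusted p = 0.510, or 0.00230 with the block).

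Most markers of other cell types stood at low levels in both gates. Of 2 measured T cell genes Lck fell from 4.86 ± 0.460 to 1.94 ± 0.494 FPKM, while Trac stood at 1.29 ± 0.759 against 0.593 ± 0.394 FPKM and Lat at 0.317 ± 0.125 against 0.359 ± 0.0656 FPKM (SD, n = 4; camera adjusted p = 0.585). Among myeloid genes Cd68 stood at 7.78 ± 1.69 against 7.67 ± 1.89 FPKM (list adjusted p = 0.894), Lyz2 at 0.293 ± 0.189 against 0.235 ± 0.214 FPKM and Itgam at 0.253 ± 0.0613 against 0.535 ± 0.0834 FPKM. No neutrophil gene was tested, and S100a9 stood at 0.121 ± 0.143 against 0.386 ± 0.550 FPKM. The NK cell gene Tyrobp (1.19 ± 0.391 against 1.41 ± 0.337 FPKM; list adjusted p = 0.826) and the platelet gene Itgb3 (4.32 ± 0.843 against 3.62 ± 1.25 FPKM; list adjusted p = 0.681) did not pass, though Itgb3 passed as higher with the block (adjusted p = 0.0439). The endothelial gene Pecam1, at 11.7 ± 4.18 against 18.6 ± 6.14 FPKM (adjusted p = 0.164; list adjusted p = 0.564), passed as lower with the block (adjusted p = 0.000222). These lists did not pass with the block (adjusted p = 0.434 for the platelet and 0.260 for the endothelial list). Nor, without the block, did the dendritic cell genes Bst2 (109.6 ± 7.22 against 95.5 ± 7.71 FPKM), Flt3 and Batf3 pass (list adjusted p = 0.521; 1 higher adjusted over the list alone, and 2 higher and 1 lower with the block). In fry the T cell list passed as lower (adjusted p = 0.0336) and the dendritic cell list as higher (adjusted p = 0.0130). B cells can also express Bst2 and Pecam1. The erythroid genes Car2 (2.97 ± 0.515 against 6.60 ± 0.981 FPKM) and Hbb-bt (0.699 ± 0.183 against 2.12 ± 0.427 FPKM) both fell (list adjusted p = 0.0249, adjusted p = 0.938 with an estimated correlation, 0.193 with the block, 0.336 without a filter on low values and 0.103 within replicates 3 and 4).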

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

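In 12 of 290 groups of 4 libraries tested, for named genes, list levels and library totals, 1 library lay far from the other 3, with a gap to its nearest neighbour, as a share of the group's range, above Dixon's critical value. Chance alone gives about 1 in 20 such groups, and no test was added for these values.

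Mapk3 in IL-10+ replicate 3 was low (14.1 FPKM against 16.9 to 17.2 in the other 3 libraries, gap ratio 0.905). Lag3 was high in IL-10+ replicate 1 (9.80 against 4.64 to 5.49 FPKM, gap ratio 0.835), and so was mt-Co3 (25.3 against 11.7 to 13.5 FPKM, gap ratio 0.862). Chaf1b was low in that library (9.65 against 11.4 to 11.7 FPKM, gap ratio 0.860). Pfkfb4 was low in IL-10- replicate 2 (1.89 against 2.66 to 2.81 FPKM, gap ratio 0.836), where Cxcl10 was high (2.91 against 1.45 to 1.56 FPKM, gap ratio 0.925). Uhrf1 was low in IL-10- replicate 1 (121.5 against 157.3 to 164.4 FPKM, gap ratio 0.834).

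The mean log2 level of the marginal zone list was high in replicate 3 of both groups, at 4.08 against 3.91 to 3.93 in IL-10+ (gap ratio 0.849) and 3.65 against 3.46 to 3.48 in IL-10- libraries (gap ratio 0.861). The glycolysis list was low in IL-10+ replicate 3 (4.45 against 4.67 to 4.71, gap ratio 0.834). The stress and heat shock list was high in IL-10+ replicate 2 (5.75 against 5.47 to 5.49, gap ratio 0.923). The NK cell list, which has 1 measured gene, was low in IL-10- replicate 1 (0.934 against 1.34 to 1.41, gap ratio 0.851).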

How the results depend on the processing

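The alternatives named here as combinations of scaling and block, voom, and fits within or with the sets of replicates were chosen after seeing the data; the others were planned. No gene called in the planned fit changed direction under any alternative. Il10 stayed called under each of the 29 alternatives run for it, at a log2 change of 2.80 to 3.71, and the count of genes changed 2-fold or more was 365 to 684. The count of 2236 genes was 1208 to 2055 when 1 library or 1 replicate number was left out. With 1 replicate number left out it was 1208 without replicate 2, 1229 without 3, 1357 without 4 and 2014 without 1, all with 3 against 3 libraries. It was 1249 at an adjusted p under 0.01, and 1106 within replicates 1 and 2 against 2647 within 3 and 4, and the cause was not tested. Terms for the pairing raised it, to 6083 with the replicate block, 4301 with replicates 1 and 2 against 3 and 4 as a term, 6416 with voom and the block, 5624 with median-of-ratios scaling and the block (46.5% of them higher), and 5666 (45.0% higher) with scaling without immunoglobulin and mitochondrial genes and the block, since variance shared within a number leaves the residual. Median-of-ratios scaling without the block called 2111 genes, 62.2% of them higher, against 53.5% in the planned fit.

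With an estimated correlation 0 lists passed, with or without the block. Without it the adjusted p was 0.153 for the plasmablast list and 0.938 for the mature B cell and regulatory B cell lists, and with the block 0.497 for all 3. The regulatory B cell list also gave 0.155 with a filter at 5 FPKM, where fewer genes are tested, 0.0793 with median-of-ratios scaling and the block and 0.0709 with scaling without immunoglobulin and mitochondrial genes and the block. The OXPHOS list of nuclear genes passed as higher with the block and either of these scalings (adjusted p = 0.0219 and 0.0327), and the list of the mitochondrial genome passed as lower with quantile normalization (0.0190) and within replicates 3 and 4 (0.0310). With 1 library or number left out, the nuclear list ranged from 0.0231 (without IL-10+ replicate 1) to 0.837, with its direction turned without IL-10- replicate 1 (0.603), and the mitochondrial list from 0.0427 (without IL-10- replicate 2) to 0.524. The cause was not tested. The block changed the call of the MYC, cholesterol, S phase and antioxidant lists, which passed with it, and of the immunoglobulin constant region and erythroid lists, which did not, and of no other list.

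Some results that were not called in the planned fit changed direction, and the cause was not tested. In fry the adjusted p, with the direction turned, was 0.925 for OXPHOS complex V, 0.966 for the TCA cycle, 0.976 for fatty acid oxidation, 0.710 for ERK cascade components and 0.982 for stress and heat shock. Without a filter on low values it was 0.830 for complex V, 0.843 for the TCA cycle and ERK cascade lists and 0.799 for stromal and endothelial markers, and with a filter at 5 FPKM 0.990 for glycolysis and 0.884 for checkpoint and adhesion molecules. With quantile normalization it was 0.873, 0.823 and 0.601 for complexes II, IV and V, 0.868 for all nuclear OXPHOS genes, 0.695 for the TCA cycle and 0.976 for stress and heat shock. With library weights it was 0.759 for complex V and 0.986 for the TCA cycle. The stress and heat shock list turned with the replicate block (0.861), with the block and an estimated correlation (0.913), with voom and the block (0.809), with the block and either scaling (0.700 and 0.743), within replicates 3 and 4 (0.483) and with the sets as a term (0.862). Within replicates 1 and 2 the TCA cycle (0.904), T cell (0.844) and NK cell (0.632) lists turned, and within 3 and 4 the complex II (0.912) and macrophage (0.673) lists did.

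The log2 change of mt-Co1 turned to 0.028 with median-of-ratios scaling and 0.021 with scaling without immunoglobulin and mitochondrial genes, each with and without the block, to 0.022 with library weights and to 0.0060 within replicates 3 and 4, and ranged from -0.107 to 0.085 with libraries left out. With quantile normalization it was -0.85 (adjusted p = 5.95e-06), the one alternative in which mt-Co1 passed. In those fits the adjusted p ranged from 0.388 to 0.968 for regulators of Il10, 0.0928 to 0.837 for complex I, 0.50 to 0.990 for complex II, 0.239 to 0.866 for complex IV, 0.453 to 0.963 for complex V, 0.388 to 0.950 for the TCA cycle, 0.792 to 0.992 for the ERK cascade, 0.542 to 0.975 for NK cell and 0.751 to 0.992 for macrophage markers.

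Of 88 named genes that were called, 61 stayed called in each fit that left out 1 library and 27 did not. Those fits had no replicate block, so spread between the numbers stayed in them. With all libraries and the block, each of the 2236 genes of the planned fit was called in the same direction. Depth limits genes near 1 FPKM, where 1 read in 1 kb is worth 0.0334 to 0.0365 FPKM.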

Other observations

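The tests of the 3 patterns below were chosen after the results were seen, except for the counts over other splits of the libraries.

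Replicates 1 and 2 differed from replicates 3 and 4, in both groups, in several of the fixed lists. The genes named here were chosen after their values were seen. The unit of this comparison was the mean of the 2 libraries of a number, so each set holds 2 units, and the list calls are those of camera at the preset correlation, of which 0 held with an estimated correlation. The amino acid and ATF4 list was higher in replicates 1 and 2 (13 of 21 genes; camera adjusted p = 2.28e-13), with Trib3 at 63.7 ± 2.41 against 13.1 ± 0.532 FPKM, Cth at 41.0 ± 5.33 against 7.59 ± 2.89 FPKM and Sesn2 at 58.1 ± 10.1 against 19.7 ± 4.91 FPKM (SD over the 4 libraries of a set, which come from 2 numbers). Replicates 3 and 4 were higher in MYC and ribosome biogenesis genes (14 of 32; adjusted p = 1.21e-13), cholesterol synthesis genes (13 of 21; adjusted p = 1.34e-11) and OXPHOS genes (7 of 77, with 1 lower; adjusted p = 1.27e-10). Of the 17 stress and heat shock genes 5 were higher and 6 lower in that set (median log2 difference -0.34, adjusted p = 0.945), and among the higher ones Hspa8 stood at 776.9 ± 85.2 against 393.3 ± 74.5 FPKM. In each replicate number the MYC list was lower and the ATF4 list higher in IL-10+ than in IL-10- cells.

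Of the immunoglobulin V segments, 4 rose more than the others. Ighv11-2 (chromosome 12, 114048241 to 114048812 of GRCm38) stood at 287.7 ± 88.7 FPKM in IL-10+ and 3.65 ± 0.522 FPKM in IL-10- cells (SD, n = 4), 78.7-fold apart. Igkv14-126 (chromosome 6, 67896172 to 67896642) stood at 615.5 ± 146.5 against 17.04 ± 2.75 FPKM, 36.1-fold apart. Ighv12-3 was 31.8-fold and Igkv4-91 11.4-fold higher. These 4 segments held ranks 1 to 4 by log2 change among the 196 measured V segments. They were singled out after their values were seen, because they form the known heavy and light chain pairs (VH11 with Vκ14-126, VH12 with Vκ4-91) of the phosphatidylcholine-binding receptors of B-1a cells. Each was called with adjusted p between 4.58e-06 and 2.15e-05 and was higher in all 4 replicate numbers.

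Segments picked for their rise lie above the rest by that choice, so they were chosen in 1 set of replicates and tested in the other. The 4 that rose most in replicates 1 and 2 were Ighv11-2, Ighv12-3, Igkv14-126 and Igkv7-33. In replicates 3 and 4 the first 3 of these rose by a log2 of 4.19 (SE 0.211) or more. The highest of the 192 segments not chosen there was Igkv4-91 at 3.23. These values argue against a uniform rise of immunoglobulin transcripts for these 3, while Igkv7-33 stood at 2.69 (SE 0.776). Chosen in replicates 3 and 4, the 4 were those of the pattern, and in replicates 1 and 2 the lowest of them, Igkv4-91, stood at 3.70 (SE 0.171), under the highest of the other segments (3.88). For Igkv4-91 a uniform rise stays open, since it was not among the 4 chosen in replicates 1 and 2. Reads shared with the 28 other measured segments of the same V families are argued against for the same 3, since the highest change among these relatives in replicates 3 and 4 was 2.18. They stay open for Igkv4-91 for the same reason, with the highest relative at 2.92 in replicates 1 and 2. Segments that were not measured cannot be judged as a source. The median excess of the 4 over the median of the other segments was a log2 of 2.81 to 3.33 in every replicate number. The 4 belong to 2 receptor pairs and were picked over all numbers. This pooled value therefore cannot decide on an expanded clone in one replicate number. Ighv11-2, Ighv12-3 and Igkv14-126, chosen in replicates 1 and 2, also rose in 3 and 4, so their rise was not confined to one number. A hypothesis is that IL-10+ cells may include more cells of the B-1 lineage, but the B-1 gene list gave camera adjusted p = 0.189, and this cannot be told apart from a difference in receptor choice among other B cells with the genes measured here. Cd5, a surface marker of B-1a cells, was at 0.255 ± 0.0566 against 0.195 ± 0.0820 FPKM, too low to be tested.

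Replicates 1 and 2 held Y-linked transcripts (Ddx3y at 18.9 to 24.7 FPKM) and replicates 3 and 4 held Xist (80.3 to 91.0 FPKM) and 0 FPKM of Ddx3y, Eif2s3y, Kdm5d and Uty. In the fit on the 4 numbers, 780 autosomal genes and 31 others differed between the sets, while the other 2 ways to part the numbers called 0 genes (115 and 100 at an unadjusted p under 0.05). Therefore sex-chromosome genes alone are not the whole difference, and the read totals of the 8 libraries, at most 1.09-fold apart, overlapped between the sets and lay under the median fold of 1.51 of the autosomal genes called. Male and female mice and a shared day or batch cannot be told apart, since 0 sets held both sexes, and both stay open. Whether the effect of the sort differed between the sets stays open. In limma's interaction test 0 of 11329 genes passed, with 315 at an unadjusted p under 0.05 without the replicate block and 846 with it, where chance gives 566. With the block, the difference in the log2 change of Il10 was -0.91 (interaction test, unadjusted p = 0.00132, adjusted p = 0.296 over all genes). Of 44 lists, with the V segments counted as 1, 8 differed between the sets by camera at the preset correlation and 0 with an estimated correlation. The V segments had a median log2 change of 2.16 in replicates 1 and 2 and 1.64 in 3 and 4 (adjusted p = 7.05e-52), and the plasmablast list 1.78 and 1.34 (adjusted p = 1.40e-11). The other 2 ways to part the 4 numbers gave 14 and 5 such lists and 419 and 421 genes at an unadjusted p under 0.05 with the block, so the gene count was highest for these sets and the list count was not, and 3 ways are too few to decide.

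The immunoglobulin share of the summed FPKM was 14.6% in IL-10+ and 4.19% in IL-10- libraries. FPKM are scaled by the read total and not by this sum, so the share does not give the size by which other genes are lowered. The summed FPKM without immunoglobulin and mitochondrial genes was taken relative to its mean over the libraries. It was 0.979 to 0.995 in IL-10+ and 0.996 to 1.02 in IL-10- libraries. After the libraries were scaled without immunoglobulin and mitochondrial genes, 786 of the 1040 fallen genes still passed as lower, with a median log2 change of -0.49 before and -0.46 after (median SE 0.0922 and 0.0936), so the larger immunoglobulin share of the IL-10+ libraries is not their whole cause. The other 254 lost their call, at a median of -0.28 before and -0.25 after (median SE 0.0792 and 0.0804), because small changes moved closer to 0. No biological explanation of the falls was tested.

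Among the 35 splits of the 8 libraries into 4 against 4, only the real split called 2236 genes or more, and 1 of 35 had as many changed 2-fold or more. This share would exclude chance for both counts only if libraries could be exchanged without regard to their replicate numbers. The numbers pair the libraries, however, and only 8 of the 35 splits part all 4 numbers, too few for a share under 0.05. The highest other split called 1555 genes and 89 by 2-fold or more. It set replicates 1 and 2 against 3 and 4, which points to the structure described above, and the other 33 splits called 0 genes. For the number of lists that pass camera at the preset correlation chance cannot be excluded, since 21 of 35 splits gave 13 lists or more, and the highest other split gave 25. Of the 8 splits that part all 4 numbers 2 gave 13 lists or more, the real one with 13 and the highest other with 13. The split of replicates 1 and 2 against 3 and 4 gave 24 lists, and 15 lists passed in the real split with the replicate block. Of those 8 splits the real one, 1 of 8, called 2236 genes without and 6083 with the block, and the highest other 0 in either fit.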
